A study of Caenorhabditis elegans with 8 samples.

How the data were processed

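Small RNAs were measured in whole animals of the nematode Caenorhabditis elegans, in 8 libraries that fall into 4 groups of 2. The groups combine 2 strains with 2 foods. The strains were N2, the standard wild type, and YY1683, which carries a mutation in zsp-1, a gene also called pid-2 and named pid-2 in the count files. The series title writes zsp-1 for the mutated gene and the genotype label of the strain writes zap-1; the group is called the zsp-1 mutant throughout. The foods were HT115 bacteria that carried the empty vector L4440 or expressed double-stranded RNA of oma-1, at 20 °C. The labels give the stage as adults on day 1 that carried eggs, and the extraction text as young adults.

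Per the labels' protocols, 20 µg of total RNA were separated on a gel, RNAs of about 18 to 35 nt were cut out, and they were cloned by a protocol that does not need a 5′ monophosphate. Such a protocol also captures the triphosphate-bearing small interfering RNAs (siRNAs) made by RNA-dependent RNA polymerases, which the labels call 22G siRNAs. The authors' deposited files hold raw counts of reads per gene, whole numbers that were not normalised, for 20191 genes, per the file headers. Per the submitters' processing notes, the tools were cutadapt 1.14, TopHat2 2.1.1 and featureCounts 1.6.0 with genome build WBcel235. The strand setting, any filter on read length or first base, and the treatment of reads that map to several places are not given in the sources used here. Reads antisense to a gene therefore cannot be told from sense reads, among them fragments of the ingested double-stranded RNA, and reads of near-identical or overlapping genes can be shared between them.

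Gene names were joined to the Ensembl annotation of the same build, by current symbol for 18960 genes and by an older name for 1060, and 171 names had no match. By that annotation 19813 genes were protein-coding, 200 were pseudogenes and 7 were long intergenic RNAs. No gene with a match was a miRNA, piRNA, tRNA, rRNA, snRNA or snoRNA gene, so these classes were not analysed here. Another gene on the opposite strand overlapped 2627 genes, and 708 overlapped a gene on the same strand.

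Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 4567 genes. Libraries were scaled by TMM, and a quasi-likelihood model with 4 group means was fitted to all 8 libraries, which leaves 4 residual degrees of freedom. Contrasts gave the mutant against wild type on each food, the mean of both, the response to oma-1 RNAi in each genotype, and the difference of the responses. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called under 0.05. Standard errors (SE) of log2 fold changes were computed as the absolute log2 fold change over the square root of the model's F statistic. The 95% intervals follow from these SE, and both are approximate for genes with few reads in an arm. Levels are the CPM values of edgeR, computed from TMM-scaled totals. No label says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

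Lists of genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 13 lists with at least 3 tested genes. Camera with an estimated correlation and fry were run beside it. The lists were the RNAi target and its paralog, germ granule proteins, the small RNA pathway, histones, loci of ERGO-1 class siRNAs, targets of nuclear silencing, spermatogenesis, oogenesis and maternal genes, meiotic chromosomes, muscle, intestine, cuticle, neurons, ribosomal proteins, stress and immunity, X-linked genes, pseudogenes and the classes of noncoding RNA. The list of histones held replication-dependent histone genes, without his-24. The design, the lists and the alternatives were fixed before the data were examined. The rule for named genes took oma-1, oma-2 and zsp-1. For the averaged genotype contrast it took up to 12 genes in each direction with the largest log2 change among called genes with a mean CPM of at least 10 and no overlap between the genotypes on either food. For the RNAi responses and their difference it took up to 5 in each direction by the same rule, and from each list up to 4 with the smallest p in the averaged genotype contrast. Other genes named below were chosen after their values were seen: rrf-1 and tofu-1 complete the calls of their list, and the members of gene families in the closing section are examples.

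Library totals ranged from 136908 to 340932 reads, so 1 read corresponds to several CPM and genes with few reads have wide errors. For genes with 1 to 3 reads in an arm, the ratio of pooled read shares is given with an exact 95% interval. Where an arm had 0 reads, the ratio was computed against a floor of 3 reads over the whole arm. These intervals and floors cover counting error only, because reads amplified by PCR are not independent molecules. On simulated counts with 200 changed genes among 4567, the averaged genotype contrast recovered 52% of 2-fold and 97% of 4-fold changes with 6 false calls. The contrast on L4440 recovered 16% and 73% with 3 false calls, and that on oma-1 RNAi 17% and 70% with 2. With no simulated change, both RNAi responses and their difference gave 0 calls each. The simulation gave every gene the same spread beyond counting error and no difference between replicate numbers, so these rates need not hold for the real libraries.

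Alternatives replaced TMM by DESeq2 size factors or by library totals, dropped the count filter, kept genes with a mean CPM of at least 10, used DESeq2 1.42.0, added the replicate number as a block, kept protein-coding genes, kept the libraries of the comparison, and left out each library in turn. Libraries are named by W (wild type) or Z (mutant), L (L4440) or O (oma-1 RNAi) and the replicate number, as in WL1. A filter at a mean CPM of 100 and thinning of all libraries to the smallest total were chosen after seeing the data, the thinning before its own result was seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.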

Results

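Small RNA reads per gene were compared between wild-type and zsp-1 mutant animals that ate control bacteria or bacteria expressing oma-1 double-stranded RNA. ZSP-1 is a protein of the Z granule, a compartment of germ granules, and oma-1 encodes a zinc-finger protein of maturing oocytes. The wild-type libraries on L4440 held 177175 and 187547 reads, and those on oma-1 RNAi 277543 and 269876. The mutant libraries on L4440 held 340932 and 136908 reads, and those on oma-1 RNAi 228338 and 172615. Libraries of 1 group differed by more than sampling noise, with a chi-square of 1.84 to 4.06 per degree of freedom. Across genes, Pearson's r of log2 CPM was 0.860 to 0.918 within groups, 0.857 to 0.944 between foods of 1 genotype and 0.599 to 0.704 between genotypes. The first principal component held 66.3% of the variance and separated the genotypes.

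The first check was the mutated gene itself. Reads at zsp-1 (pid-2, chromosome I, 93024 to 94884) were 11.5-fold lower in the mutant. Wild-type libraries had 94, 57, 116 and 92 reads, or 408.5 ± 95.2 CPM (SD, n = 4). Mutant libraries had 14, 2, 9 and 4 reads, or 31.8 ± 11.9 CPM (SD, n = 4). The log2 fold change was -3.53 (SE 0.31, adjusted p = 8.08e-10, edgeR's quasi-likelihood test). These are small RNA reads and not the messenger RNA, and the gene overlaps another on the opposite strand, so the value goes with the labels but does not show the mutation.

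**Figure D1:**
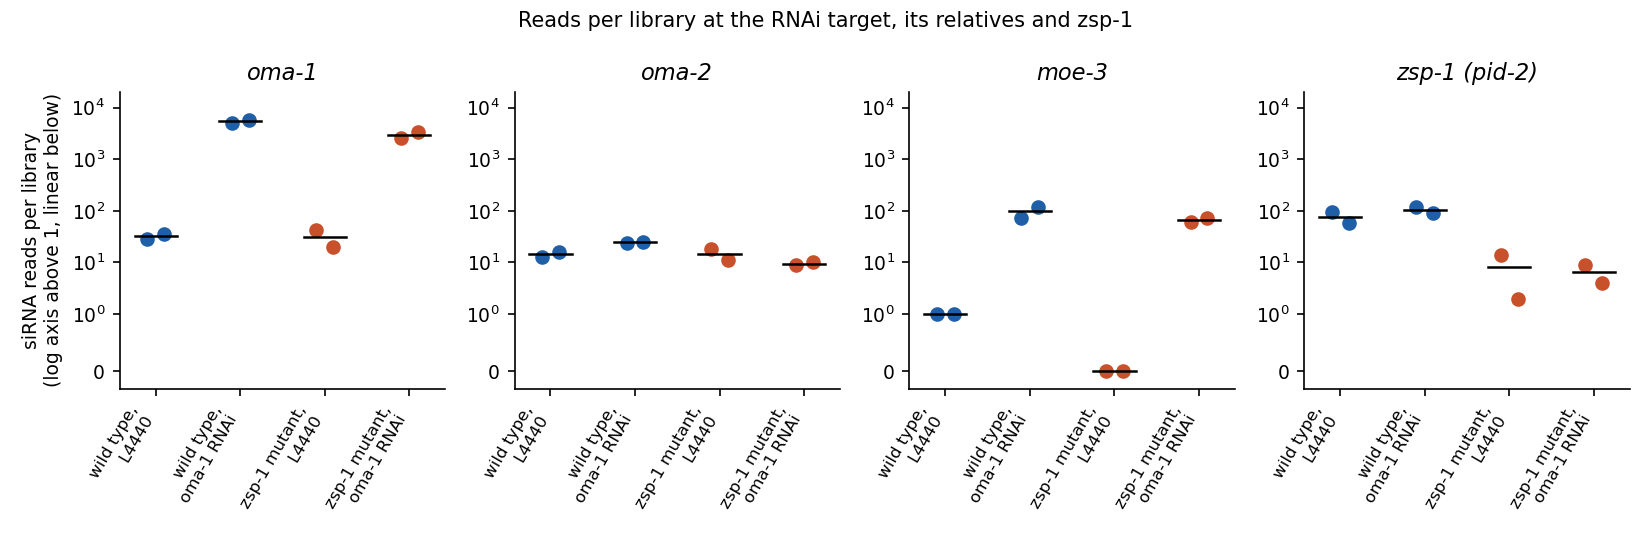
Reads per library at oma-1, oma-2, moe-3 and zsp-1 (pid-2) in the 4 groups, with 1 point for each of the 2 libraries and a line at their mean. The vertical axis is logarithmic above 1 read and linear below. oma-1 lies at 20 to 42 reads on L4440 and at 2541 to 5789 reads on oma-1 RNAi, and moe-3 at 0 to 1 and 60 to 121 reads.

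The series asks how small RNAs differ between wild-type and zsp-1 mutant animals. Averaged over both foods, small RNA reads rose at 516 genes and fell at 540 genes of 4567 tested. The largest rise was at ZK673.4, with 3 reads over the 4 wild-type libraries and 1078 over the 4 mutant libraries, a ratio of 392 (95% counting interval 134 to 1904). The cadherin gene cdh-5 rose from 18.8 ± 17.9 to 1443 ± 298 CPM (SD, n = 4 each), and the myosin VI gene spe-15, which is needed for sperm formation, rose from 13.2 ± 10.2 to 1374 ± 469 CPM (SD, n = 4 each). In the opposite direction, F31C3.6 had 158 reads in wild type and 0 in the mutant, at least 48.3-fold lower at a floor of 3 reads over the group. The insulin-like peptide gene ins-17 fell from 366.9 ± 64 to 14.7 ± 13.4 CPM (SD, n = 4 each).

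The other genes with large rises included vps-50, which acts in the maturation of dense-core vesicles. It held the most reads among them and went from 82.5 ± 41.1 to 5464 ± 957 CPM (SD, n = 4 each), a log2 fold change of 6.04 (SE 0.33). The xanthine dehydrogenase gene xdh-1 rose by 6.43 on the log2 scale (SE 0.44), the nuclear hormone receptor gene nhr-47 by 6.19 (SE 0.34), and ltd-1 by 6.49 (SE 0.43). The Nudix hydrolase gene ndx-6 rose by 6.01 (SE 0.34), the glycosyltransferase gene gly-11 by 5.95 (SE 0.40), F14B4.1 by 6.08 (SE 0.43) and K07A12.5 by 5.99 (SE 0.34). The 4 wild-type libraries together held 5 reads at ltd-1, 7 at xdh-1, 8 at gly-11 and 9 at F14B4.1, so the sizes of these rises are uncertain. In other fits the log2 change reached 8.24 at ltd-1, 8.63 at xdh-1, 8.31 at gly-11 and 8.08 at F14B4.1. chst-1, a carbohydrate sulfotransferase gene, had 2 wild-type and 165 mutant reads, a ratio of 90.0 (24.5 to 749). The adjusted p of these 12 rising genes was at most 6.91e-10. ZK673.4 lies on chromosome II (10452920 to 10455200), cdh-5 on IV (8668941 to 8676542), spe-15 on I (1446497 to 1465358) and vps-50 on III (10869193 to 10874528). nhr-47, K07A12.5 and gly-11 overlap a gene on the opposite strand and ndx-6 a gene on the same strand, so their reads are uncertain between the overlapping genes.

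Most of the 12 genes with the largest falls had almost no reads left in the mutant. K08D12.4 went from 344 to 3 reads, 105-fold lower (35.7 to 512), and Y48C3A.1 from 196 to 1 read, 180-fold lower (31.9 to 7132). F23B12.4 went from 165 to 3 reads, 50.4-fold lower (16.95 to 247), and sup-1 from 102 to 3 reads, 31.2-fold lower (10.4 to 154). The neuropeptide gene nlp-12 went from 60 to 1 read, 55-fold lower (9.50 to 2208), T14G10.8 from 56 to 1, 51.3-fold lower (8.84 to 2063), and Y41D4A.7 from 45 to 1, 41.3-fold lower (7.04 to 1665). The F-box gene fbxc-28 went from 63 to 3 reads, 19.3-fold lower (6.29 to 95.9). K02E7.12 changed by -5.81 on the log2 scale (SE 0.42), ins-17 by -5.09 (SE 0.38) and the X-linked gene F59C12.4 by -4.78 (SE 0.31). The adjusted p of these 12 falling genes was at most 5.45e-05. F31C3.6 lies on chromosome I (15053617 to 15059003), K08D12.4 on IV (1707296 to 1708691) and ins-17 on III (4476888 to 4477583). F31C3.6, F23B12.4 and Y41D4A.7 overlap a gene on the opposite strand and T14G10.8 a gene on the same strand.

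The median log2 fold change was 1.66 among all rising genes and -1.62 among all falling genes. The median over all tested genes was -0.08 with TMM and -0.19 with scaling by library totals, so single changes are relative to a centre that depends on the scaling. With totals 477 genes rose and 675 fell. At 136908 reads per library, 8364.5 ± 183.5 genes had a read in wild type and 7570.5 ± 107.8 in the mutant (SD, n = 4 each, p = 0.0286, exact permutation test, two-sided). The 20 most counted genes held 12.7 ± 0.84% of reads in wild type and 10.6 ± 1.11% in the mutant (SD, n = 4 each, p = 0.0571, exact permutation test, two-sided), which did not pass 0.05.

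The genotype contrast was also made separately on each food. The group means come from libraries that the other contrast does not use, but both share the scaling, the filter and the estimates of spread of 1 fit. On L4440, 399 genes rose and 350 fell in the mutant, and on oma-1 RNAi 382 rose and 337 fell. Of these, 325 rose on both foods and 244 fell on both, and 0 were called in opposite directions. Independent lists of these sizes would share 33.4 rising and 25.8 falling genes, and the shared fit can raise the overlap above these numbers. Among the 899 genes called on either food, 881 (98.0%) had the same sign on both. Pearson's r of the log2 fold changes was 0.865 and Spearman's rho 0.661 across 4567 genes, which are not independent replicates. The number of falls depended on the test and on single libraries. On L4440, 310 genes rose and 172 fell with DESeq2, and 329 rose and 145 fell without ZL1. On oma-1 RNAi, 303 rose and 180 fell with DESeq2, 313 rose and 174 fell without WO2, and 327 rose and 155 fell without ZO1.

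**Figure D2:**
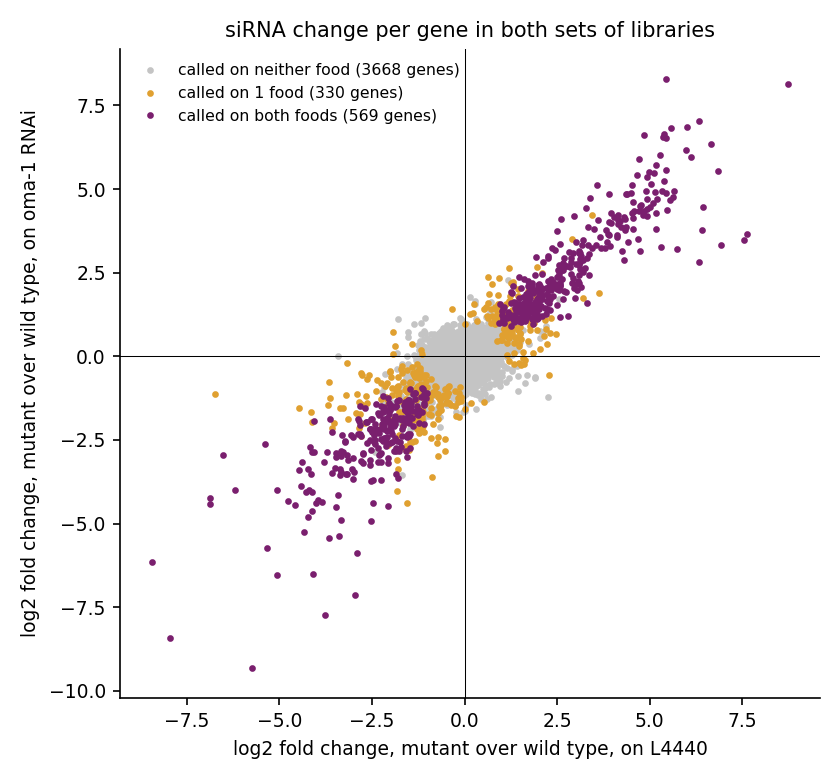
Log2 fold change of mutant over wild type on L4440 (horizontal axis) and on oma-1 RNAi (vertical axis), with 1 point for each of 4567 genes. Purple points are the 569 genes called on both foods at an adjusted p under 0.05, orange points the 330 called on 1 food and grey points the other 3668; the purple points lie in the quadrants where both changes have the same sign.

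In the small RNA pathway list, 5 of 30 tested genes rose in the mutant, 1 fell and 24 were not called. sid-1, which encodes a channel for double-stranded RNA, rose 3.64-fold from 991.9 ± 267 to 3612 ± 659 CPM (SD, n = 4 each, adjusted p = 1.03e-06). rde-11, a factor in the amplification of siRNAs, rose 2.84-fold (log2 1.51, SE 0.24), the nuclear RNAi gene nrde-1 rose 2.42-fold (log2 1.27, SE 0.24), and rde-4, whose protein binds double-stranded RNA with Dicer, rose from 257.3 ± 70.3 to 517.2 ± 48.3 CPM (SD, n = 4 each). tofu-1, a piRNA biogenesis gene, rose by 0.91 (SE 0.26), and its call was lost without ZL1 (adjusted p = 0.226) or ZO1 (0.0712). The RNA-dependent RNA polymerase gene rrf-1 had a log2 change of -0.85 (SE 0.23). Over the list alone 6 genes passed, adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.392), and its median of -0.02 and mean of 0.20 differ in sign. sid-1 lies on chromosome V (5119939 to 5126916) and rde-11 on IV (13105323 to 13106927); nrde-1 overlaps a gene on the opposite strand.

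Loci of ERGO-1 class siRNAs, a set whose siRNAs depend on the Argonaute ERGO-1, held 3 genes that fell in the mutant. Of 11 tested loci, 0 rose and 8 were not called, with a median log2 fold change of -0.57, and 6 passed adjusted over the list alone. C18D4.6 fell from 236.7 ± 39.4 to 30 ± 10.4 CPM and E01G4.5 from 2709 ± 609 to 786 ± 168 CPM (SD, n = 4 each), while Y17D7B.4 fell by 0.58 on the log2 scale (SE 0.21, adjusted p = 0.0433) and lost its call whichever library was left out. Its adjusted p was 0.0505 without WL1, 0.174 without WL2, 0.0961 without WO1, 0.0883 without WO2, 0.105 without ZL1, 0.164 without ZL2, 0.105 without ZO1 and 0.108 without ZO2. F55C9.3 was not called (log2 -0.66, adjusted p = 0.0558) but passed with library totals (0.0245). X-linked genes also had more falls than rises. Of 217 tested, 77 fell, 29 rose and 111 were not called, with a median of -0.45, and 123 passed adjusted over the list alone. The linker histone gene hil-3 fell from 1424 ± 135 to 154.6 ± 26 CPM, whereas gfi-3 rose from 197.3 ± 32.3 to 1593 ± 161 CPM and F39C12.1 from 185.1 ± 3.18 to 1214 ± 18.4 CPM (SD, n = 4 each).

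The ERGO-1 and X-linked lists were the 2 lists called in the averaged genotype contrast (camera adjusted p = 0.0425 for each). With an estimated correlation the adjusted p was 0.648 for the ERGO-1 loci and 0.709 for the X-linked genes, so neither call held in that test. No list passed that test in any of the 6 comparisons (lowest adjusted p 0.648), so failing it does not set these lists apart. Both calls were also lost without any 1 of 4 libraries. Both lists were lower in replicate 1 in all 4 groups, with medians from -0.268 to -0.14 for the ERGO-1 loci and from -0.34 to -0.267 for the X-linked genes. Leaving out a wild-type replicate 2 or a mutant replicate 1 can therefore shrink the fall by itself. These fits cannot decide whether the calls rest on single libraries. The adjusted p of the ERGO-1 loci was 0.0998 without wild-type replicate 2 on L4440, 0.144 without wild-type replicate 2 on oma-1 RNAi, 0.0926 without mutant replicate 1 on L4440 and 0.08 without mutant replicate 1 on oma-1 RNAi. For the X-linked genes the values were 0.106, 0.144, 0.0926 and 0.111 in the same order. On L4440 alone the neuron list was called (camera adjusted p = 0.0466, and adjusted p = 0.707 with an estimated correlation), and on oma-1 RNAi alone the X-linked list (0.00295, and adjusted p = 0.757 with an estimated correlation). With fry in the averaged contrast the ERGO-1 loci (adjusted p = 0.0371) and the neuron list (0.0374) passed, and the X-linked genes did not (0.125).

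**Figure D3:**
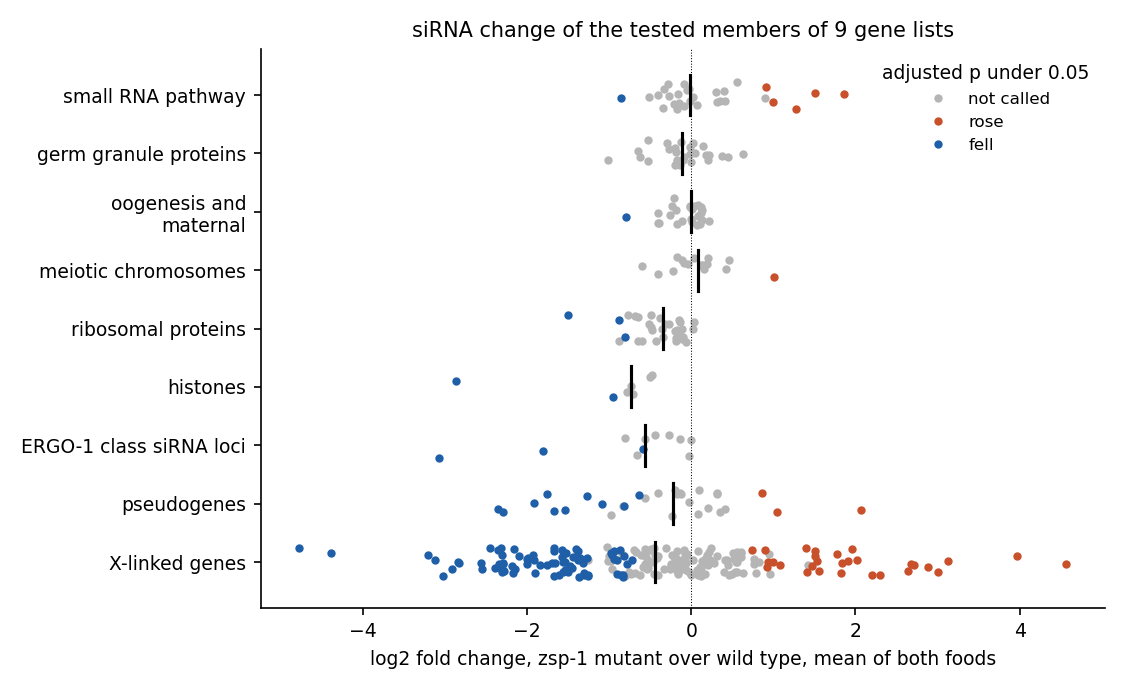
Log2 fold change of mutant over wild type, averaged over both foods (horizontal axis), for the tested members of 9 gene lists, with 1 point per gene and a black line at each list's median. Orange points rose, blue points fell and grey points were not called at an adjusted p under 0.05; the medians run from -0.73 for the histones to 0.08 for the meiotic list, and 77 X-linked genes fell while 29 rose.

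None of the 28 tested germ granule genes was called; mut-16 (log2 -0.65, adjusted p = 0.0702), deps-1 (-0.63, 0.0835) and glh-1 (-0.53, 0.0957) came closest with C06A5.6 (-0.53, 0.0763). With library totals these 4 passed (adjusted p = 0.0331, 0.0456, 0.0299 and 0.0128), and they also passed with the replicate number as a block. The absence of calls therefore depends on the scaling and on how the replicate numbers are treated. On single foods, 1 of the 28 genes rose on L4440, and glh-1 fell on oma-1 RNAi (log2 -0.93, adjusted p = 0.0465). Among 25 oogenesis and maternal genes daz-1 was the 1 call (log2 -0.80, SE 0.28, adjusted p = 0.037), which was lost with DESeq2 (adjusted p = 0.234) and without WL1 (0.0748), WL2 (0.0536), WO1 (0.183), ZL2 (0.138) or ZO1 (0.166). Among 16 genes of meiotic chromosomes him-8, which acts at the X chromosome pairing centre, rose by 1.01 (SE 0.27) and lost its call with DESeq2 (adjusted p = 0.0702) and without ZL1 (0.0621) or ZO1 (0.0614). The medians of these lists were -0.12, -0.01 and 0.08, and 0, 0 and 1 genes passed adjusted over the list alone. Of 6 spermatogenesis genes 2 rose and 2 fell: spe-15 and spe-41, a calcium channel gene (log2 1.02, SE 0.24), rose, and spe-47 (-2.26, SE 0.37) and ssp-16 (-2.27, SE 0.57) fell. The call of ssp-16 was lost with DESeq2 (adjusted p = 0.149) and without WL1 (0.155) or WO1 (0.204). Of 5 targets of nuclear silencing C41D11.6 fell (-0.66, SE 0.21, adjusted p = 0.0245) and lost its call with DESeq2 (0.0602) and without WL2 (0.0766), WO2 (0.076), ZL1 (0.136), ZL2 (0.0584) or ZO1 (0.109), while bath-45 (-0.08, SE 0.24), B0250.8 (-0.07, SE 0.23) and C38D9.2 (-0.55, SE 0.21) were not called; C38D9.2 passed with library totals (0.00449). The camera adjusted p was 0.684, 0.751, 0.751, 0.392 and 0.517 for these 5 lists in the order given.

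Among the remaining lists, 2 of 7 replication-dependent histone genes fell, and his-41 went from 66.2 ± 12.7 to 7.90 ± 5.67 CPM (SD, n = 4 each). The X-linked gene his-24, left out of this list, fell from 5697 to 3213 CPM (adjusted p = 0.00629 in edgeR's test). his-67 and his-35 were not called, but both passed with the replicate number as a block, and his-67 also with library totals. his-37 had a log2 change of -0.96 (SE 0.34, adjusted p = 0.0434), and its call was lost without WL2 (adjusted p = 0.924), WO2 (0.232), ZL1 (0.191) or ZO1 (0.161) and with DESeq2 (0.175). Of 33 ribosomal protein genes rpl-11.1 (-0.88, SE 0.26), rpl-3 (-0.81, SE 0.26) and rps-21 (-1.50, SE 0.53) fell, and the calls of all 3 were lost with DESeq2. Without single libraries rpl-11.1 lost its call for WL2 (adjusted p = 0.103), WO2 (0.0562), ZL1 (0.125) and ZO1 (0.112), and rpl-3 for WL2 (0.19), ZL1 (0.124) and ZO2 (0.0742). The call of rps-21 was lost without WL1 (0.0655), WL2 (0.138), WO1 (0.0785), WO2 (0.083), ZL1 (0.142), ZL2 (0.0549) or ZO1 (0.221). Of 7 cuticle collagens col-38 rose from 119.9 ± 45.3 to 505.4 ± 138 CPM (SD, n = 4 each) and col-71 by 0.70 (SE 0.24), and col-97 (-2.40, SE 0.56) and col-60 (-1.32, SE 0.41) fell. The call of col-71 was lost with DESeq2 (adjusted p = 0.053) and without WL1 (0.14), WO1 (0.156), ZL2 (0.243) or ZO2 (0.157). That of col-60 was lost with DESeq2 (0.137) and without WL2 (0.129), WO2 (0.0814), ZO1 (0.0567) or ZO2 (0.056), and that of col-97 without WL2 (0.0504). Of 3 neuronal genes ric-19 rose from 1 to 59 reads, a ratio of 64.4 (11.11 to 2585), egl-21 rose by 1.48 (SE 0.30) and snb-1 was not called (0.11, SE 0.40). Of 30 pseudogenes 3 rose and 10 fell, among them W06A11.4 (2.06, SE 0.23), F52G3.3 (-2.30, SE 0.30), Y82E9BR.1 (-1.54, SE 0.27) and Y73B3A.7 (-2.35, SE 0.42). Most of the falling pseudogenes were X-linked genes already counted above: C09G1.3, F52G3.3, F52G3.4, Y73B3A.7, fbxa-46, fbxc-37 and fbxc-38. Outside X, F37H8.2, W05H12.2 and Y82E9BR.1 fell, and W06A11.4, Y71A12B.15 and snpc-3.3 rose. The camera adjusted p was 0.0561, 0.0571, 0.751, 0.0555 and 0.174 for these 5 lists. The 13 muscle and 14 intestine markers had 0 tested members and held 0.00274% and 0.00117% of all reads. The stress list had 1 tested gene, hsp-4 (log2 -0.41, adjusted p = 0.383).

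On oma-1 RNAi, small RNA reads at oma-1 (chromosome IV, 8888976 to 8890999) rose 113-fold in wild type; fragments of the ingested RNA were not told apart from siRNAs. The level went from 180.6 ± 20.4 CPM on L4440 to 20500 ± 3440 CPM on oma-1 RNAi (SD, n = 2 each), from 29 and 35 reads to 5076 and 5789. The log2 fold change was 6.82 (SE 0.47, adjusted p = 3.8e-10). Reads also rose at moe-3, a gene of the same zinc-finger family (chromosome II, 13160545 to 13165733), from 1 read in each L4440 library to 74 and 121 on oma-1 RNAi, a ratio of 64.7 (17.7 to 538; adjusted p = 5.49e-06). The paralog oma-2 (chromosome V, 8029439 to 8031214) was not called, with 13 and 16 reads on L4440 and 24 and 25 on oma-1 RNAi, a log2 fold change of 0.17 (95% interval -0.66 to 0.999).

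In wild type oma-1 and moe-3 were the 2 genes called, and 0 genes fell. At an unadjusted p under 0.05 there were 135 genes, and DESeq2 also called 2. More genes passed with the replicate number as a block, most of them falls. Most calls with other settings were falls: 21 of 26 with no filter on low counts, 11 of 13 with the 4 wild-type libraries alone and 26 of 38 without wild-type replicate 2 on L4440, with oma-1 and moe-3 among the calls each time. No list was called in this contrast; the lowest camera adjusted p was 0.15, for the ERGO-1 loci and the pseudogenes.

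The zsp-1 mutant also gained small RNA reads at oma-1 on oma-1 RNAi. The level went from 152.1 ± 31.5 to 17080 ± 8340 CPM (SD, n = 2 each), from 42 and 20 reads to 2541 and 3402, with a log2 fold change of 6.85 (SE 0.47, adjusted p = 4.39e-10). moe-3 went from 0 reads in both L4440 libraries to 60 and 74, at least 52.2-fold higher at a floor of 3 reads over the group (adjusted p = 7.05e-07). oma-2 was not called, with 18 and 11 reads on L4440 and 9 and 10 on oma-1 RNAi and a log2 fold change of -0.42 (95% interval -1.40 to 0.55). oma-1 and moe-3 were again the 2 calls, 129 genes had an unadjusted p under 0.05, DESeq2 called 2, and no list was called (lowest camera adjusted p 0.149). More genes passed here too with the replicate number as a block.

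The last comparison asks whether the response to oma-1 RNAi differed between the genotypes. At oma-1 the difference of the log2 responses was 0.03 (SE 0.55, 95% interval -1.10 to 1.16, adjusted p = 1). Differences within that interval stay compatible with these libraries, so equal responses were not shown. On oma-1 RNAi itself, oma-1 reads in the mutant differed from wild type by -0.26 on the log2 scale (95% interval -0.98 to 0.45, adjusted p = 0.788), which is within the spread between libraries. The moe-3 reads amounted to 1.46% and 2.09% of the oma-1 reads in the wild-type libraries on oma-1 RNAi and to 2.36% and 2.18% in the mutant libraries. At oma-2 the difference of the responses was -0.59 (95% interval -1.87 to 0.69).

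Across 4567 genes 0 passed in edgeR's test of the difference, 113 had an unadjusted p under 0.05, and DESeq2 also called 0. With the replicate number as a block some genes passed. Without filter on low counts 1 gene passed, and without wild-type replicate 2 on L4440 6 genes passed. Of the lists the X-linked genes passed (median log2 difference -0.22, camera adjusted p = 0.0356), with 0 members called singly and adjusted p = 0.988 with an estimated correlation.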

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

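The test of other splits, that of depth and the ratio of rising to falling calls without abundant genes were planned before their results were seen; the test of kept direction, both tests of a germline share, both tests of moe-3 and both tests of the X-linked list were chosen only after the result was seen. The prediction for the share of moe-3 reads was reworded after the result was seen. A planned test of a lower germline share (ratio 1.11, set by the neuron list) and a later test (lower limit -0.117) were dropped as void, because scaling centres the changes.

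The X-linked genes stood out because their response to oma-1 RNAi differed between the genotypes in a test of the difference, with a median of -0.218 on the log2 scale. Their median response was 0.045 in wild type and -0.11 in the mutant, and 0 of the 217 genes passed singly. The tables argue against reading this as a firm difference. Without 1 library at a time the adjusted p of the list ranged from 3e-05 to 0.753 and exceeded 0.05 in 4 of 8 fits. The call may rest on single libraries, but these fits cannot decide it. The list was lower in replicate 1 in all 4 groups (medians from -0.34 to -0.267), so leaving out 1 library also shifts the difference. The list passed with library totals (adjusted p = 0.0239) and with the replicate number as a block (0.02). With the correlation between its genes estimated at 0.167 the adjusted p was 0.988, so genes that vary together may have been counted as independent. No list passed that test in any of the 6 comparisons, so it cannot decide this. A true difference between the genotypes stays open.

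The number of genes that changed with genotype was set against chance and technical explanations. Dividing the 8 libraries by genotype gave 1111 genes, and the other 34 ways to divide them into 4 and 4 gave at most 2. So 1 of 35 splits reached the real count. Every other split puts both genotypes on each side, which widens the spread there, so this test cannot exclude chance. The tables argue against depth alone, since a share of 0.97 of the calls kept direction at an unadjusted p under 0.05 after thinning to 136908 reads. A lower share of germline RNA was not settled. The median of 41 oogenesis and meiotic genes lay at least 1.5 log2 units (lower 95% limit) above that of the falling genes whatever the scaling. The falling genes were picked for falling in this contrast, so part of this gap was built in and it cannot decide. The 10 tested cuticle and neuron genes moved apart (chi-square 18.1 per degree of freedom around a common change) instead of rising alike. This argues against a common rise of these 10 genes only. Without the 20 most counted genes and without TMM, a share of 0.999 of the calls kept direction, but the ratio of rising to falling calls became 0.652 of its value (462 rose and 742 fell), so the balance of gains and losses cannot be told apart from a shift of totals. An effect of the mutation on which genes are targeted is the hypothesis the design names, and it is not separated here from other differences between the strains.

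The rise of moe-3 on oma-1 RNAi drew attention because it was the 1 gene besides the target that passed in both genotypes. Silencing that spreads to every relative of the target is argued against, since the upper 95% limit of the oma-2 response was 0.999 on the log2 scale in wild type and 0.55 in the mutant. A constant share of reads against oma-1 that is counted at moe-3 may account for it, because the mutant share over the wild-type share was 1.28. The shares of the genotypes did not overlap (pooled 1.79% against 2.25%, Fisher's exact p = 0.0478 for counting error only), yet a response of moe-3 itself would give the same numbers, so both stay open. Similarity between both genes was not analysed here.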

How the results depend on the processing

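Of 58 calls at named genes, 46 held in every alternative fit and every fit without 1 library, and none of the others turned direction. For the genotype contrast averaged over foods, counts ranged from 792 with DESeq2 to 1361 with the replicate block and from 890 to 999 without 1 library, and of the thinned libraries' 941 calls 905 were shared. A mean CPM of at least 100, which leaves 2146 genes, gave 634 calls there and 465 on oma-1 RNAi. On L4440 DESeq2 gave 482, and fits without 1 library 474 to 741; on oma-1 RNAi these fits gave 482 to 769. The response in wild type gave 26 calls with no filter on low counts, 13 with the libraries of the comparison alone and 2 to 38 without 1 library; that in the mutant gave 2 to 3 without 1 library. The difference of the responses gave 1 with no filter on low counts and 0 to 6 without 1 library. For the lists, 2 of which passed, an estimated correlation left 0, library totals gave 5 and fits without 1 library 0 to 5. Apart from the smaller number of genes or samples where one was named, the cause was not tested. Where a group is left with 1 library, that library is assumed to vary like the others. The log2 change of oma-1 kept its call in each genotype in every fit, from 6.64 to 7.05 in wild type and from 6.24 to 7.28 in the mutant without 1 library.

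The replicate numbers are shared between groups, but no label says what they stand for, so with 2 numbers the libraries were treated as unpaired; fits with the block had been run before this was settled. Differences between replicate 1 and 2 correlated across genes between groups by 0.171 to 0.347, and the second principal component (10.6% of variance) separated the numbers. Between them 544 genes differed, 133 higher and 411 lower in replicate 1. The main fits count this shared difference as spread within groups, so it can cost calls, also in fits without 1 library. With the replicate block the wild-type response gave 24 calls (19 of them falls), the mutant response 12, the difference 2 and the lists 5 (adding neurons, histones and ribosomal proteins, each 0.0335). Between the numbers the X-linked list differed (adjusted p = 1.08e-06, and adjusted p = 0.0398 with an estimated correlation). The block also called mut-16 (0.0102), deps-1 (0.0103), glh-1 (0.00433), C06A5.6 (0.000811), F55C9.3 and C38D9.2. A planned test of the X-linked difference with the block gave an adjusted p of 0.02, against that explanation, and was dropped because a balanced block cannot change the estimate. A test of the spermatogenesis list between the numbers (adjusted p = 0.0852) was also dropped. Depth limits genes with few reads: of the genes that rose 38 had a mean under 10 CPM in wild type, and of those that fell 47 in the mutant.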

Other observations

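The tests of neighbouring genes and of exon length were planned before their results were seen, and the tests by gene family and by chromosome were chosen after the list results were seen. Families of genes whose names share a prefix moved in opposite directions in the mutant. Of 49 families with at least 8 tested members, 4 passed Fisher's exact test across genes at an adjusted p under 0.05. Genes of 3 F-box families, whose proteins serve as substrate receptors of ubiquitin ligases, fell more often than other tested genes: 10 of 16 tested fbxb genes fell and 0 rose (odds ratio 12.6, adjusted p = 0.000199), 7 of 12 fbxc genes fell and 2 rose (10.6, 0.00391), and 12 of 32 fbxa genes fell and 5 rose (4.55, 0.00391). The fall was from 402.5 to 19.5 CPM at fbxb-56 (log2 -4.54, SE 0.34) and from 101.8 to 10.1 CPM at fbxa-136 (-3.72, SE 0.49), whereas fbxa-192 rose from 87.1 to 729.9 CPM (3.04, SE 0.25). In contrast 10 of 23 tested bath genes, which encode BTB and MATH domain proteins, rose and 3 fell (odds ratio 6.13, adjusted p = 0.00391). bath-36 rose from 66.1 to 952.2 CPM (3.83, SE 0.33) and bath-1 from 169.4 to 1006 CPM (2.54, SE 0.25), while bath-45 stayed at 6728 ± 1460 and 6375 ± 959 CPM (SD, n = 4 each), within its spread. The median of each family kept its sign with DESeq2 size factors and with library totals. Among the falling F-box genes, fbxa-46, fbxc-37 and fbxc-38 are annotated as pseudogenes. They are X-linked, as are fbxa-40 and fbxa-170, so these falls are also counted among the X-linked genes. Members of a family are similar, so reads shared between them limit the family counts, and genes are not independent replicates.

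By chromosome, falling genes made up 35.5% of tested genes on X and 10.6% elsewhere (odds ratio 4.62, adjusted p = 8.15e-20, Fisher's exact test across genes, 12 tests). On chromosome III falling genes made up 8.38% and elsewhere 12.8% (odds ratio 0.624, adjusted p = 0.000611). The genes elsewhere include those on X, so part of this difference is the excess on X. Chromosomes I, II, IV and V held 10.7%, 12.3%, 10.1% and 12.5%. Rising genes were 13.4% on X and 11.2% elsewhere (odds ratio 1.22, adjusted p = 0.553). Genes are not independent replicates, and the set test of the X-linked list with an estimated correlation did not pass. No list passed that set test in any of the 6 comparisons.

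A hypothesis was that neighbouring genes change together. Leaving out overlapping genes, 68 of 378 rising genes had another rising gene within 10 kb, against a mean of 61.8 in 10000 permutations within chromosomes (permutation p = 0.27, one-sided). For falling genes 65 of 440 had such a neighbour against a mean of 75.1 (permutation p = 0.84, one-sided). At this distance the tests gave no excess of neighbours in either direction.

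A second hypothesis was that transcript length separates gains from losses. The merged exon length had a median of 1635 nt in rising genes, 1068.5 nt in falling genes and 1803 nt in genes not called. Within 5 classes of mean CPM, the mean log2 length of rising genes exceeded that of falling genes by 0.553, a ratio of 1.47 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). Length may therefore go with the direction of change in these libraries, as a pattern across genes that does not say what links them.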
